A study of Mus musculus with 6 samples.

How the data were processed

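Total RNA was extracted from pools of dissected embryonic day 14 MGE tissue, and 6 libraries in 2 groups were sequenced. Per the submitters' processing notes, Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and DESeq2 were used with the build GRCm38. The annotation release and the strand setting are not given in the sources used here, so antisense partners cannot be told apart from the genes they overlap. The authors deposited raw read counts per Ensembl gene, which were the input of each test here. The authors also deposited a normalized signal table. In the columns checked, those of WT 1, WT 2, WT 3 and KO 3, each value equalled the raw count divided by 1 factor per library, with a largest relative deviation of 5.1e-10. That table held 17983 genes, those with a total count of at least 61, and was used only for this check. In it, 2 value columns share 1 name and were not used here.

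Groups and replicate numbers came from the labels, which describe each library as a separate pool of embryos. Gene symbols, positions, biotypes and exonic lengths came from GENCODE M21 (GRCm38), in which 49056 of 49315 gene IDs were found and 259 were not. Genes passing filterByExpr (minimum count 10, minimum total 15) were kept, which left 18079. TMM factors were applied, and WT and KO libraries were compared with the robust quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 with Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change is its size over the square root of F. The biological coefficient of variation was 9.52%. Tested on simulated data for this comparison (17834 genes tested), the procedure recovered 79% of genes changed 1.5-fold and 97% of genes changed 2-fold, and 7.853% of its calls were false. The simulation changed 100 genes per fold, all above a minimum expected count, with a spread set by expression level and no library set apart. In the real data 20.2% of tested genes were called and KO 1 stood apart, so these rates may not hold there.

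The design, the rule for named genes and 28 gene lists were fixed before the data were examined. Named genes were Prdm16 and Pdzrn3 and, per direction, the 10 called genes with the largest fold and then the 5 with the smallest p, with a mean of at least 1 CPM and all 3 libraries of one group above or below those of the other. Unnamed gene models, Rik clones and listed sex-linked genes were skipped. Up to 4 members of each list, those with the smallest unadjusted p, could be named; Slc1a3, Dll3, Mfng, Hba-a1, Hba-a2 and Xist were named outside this rule after their values were seen, as were the genes named from lists written after a first look at the data. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation of 0.01 and at least 5 tested members, again with an estimated correlation, and with fry. Correlations between libraries and principal components used the same log2 CPM values.

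Alternatives fixed in advance were other scalings, no or a stricter filter on low counts, DESeq2 1.42.0, limma voom, no robust spread, the replicate number as a block, each library left out, other thresholds and a test against a fold of 1.2. A male share covariate, a restriction to protein-coding genes and removal of each library's trend on exonic length were added after the data had been seen. The main comparison was fixed in advance as unpaired, because the labels do not say that replicate numbers pair the pools. Same-numbered WT and KO libraries, compared afterwards, did not deviate together. Intervals on shares of counts cover counting error only, since reads without molecular identifiers are not independent molecules.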

Results

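RNA-seq gene counts were obtained from the medial ganglionic eminence (MGE) of mouse embryos at embryonic day 14. The MGE is the ventral forebrain zone in which many cortical interneurons are born. Both groups carried Nkx2.1-Cre, which drives recombination in MGE progenitors, and the Ai14 reporter. The WT group had intact Prdm16, and the group labelled KO was homozygous for a floxed Prdm16 allele. Each group held 3 libraries, and each library was made from 1 pool of 3 embryos (6 eminences). Total counts were 46301483, 33188277 and 38157336 in WT 1 to 3 and 44533405, 36517047 and 55552298 in KO 1 to 3. The comparison asks which transcripts differ in the MGE when Prdm16, a zinc finger transcription factor of neural progenitors, is deleted in this lineage. Values are mean CPM (read counts scaled to a common library size) ± SD over 3 libraries, and adjusted p-values of single genes are from edgeR.

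Prdm16 itself did not differ between the groups. The gene (ENSMUSG00000039410, GRCm38 chromosome 4, 154316125 to 154636873) had 49.4 ± 5.55 CPM in WT and 50.2 ± 4.02 CPM in the pools labelled KO. Its counts were 2572, 1574 and 1743 in WT 1 to 3 and 2376, 1870 and 2527 in KO 1 to 3. The log2 fold change was 0.02 (SE 0.09, edgeR adjusted p = 0.884), and the lower 95% bound of the fold was 0.884. Counts were per gene, and which exons the floxed allele loses is not given in the sources used here, so it stays open whether this gene can check the KO label. Each direction below rests on that label alone. Pdzrn3, which encodes a ubiquitin ligase, had 16.3 ± 1.04 CPM in WT and 16.4 ± 1.42 CPM in the pools labelled KO (log2 fold change 0.01, SE 0.09, edgeR adjusted p = 0.956).

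In the pools labelled KO 16 of 21 radial glia genes and 10 of 23 Notch pathway genes were higher, while 9 of 17 GABAergic neuron genes, 10 of 25 migration genes and 12 of 19 genes of the lateral and caudal ganglionic eminences were lower. These are 5 of the 10 lists that passed camera with a preset correlation, and none of them passed with an estimated correlation (adjusted p = 0.287, 0.314, 0.486, 0.647 and 0.647). Effects of embryo age and of neighbouring tissue in the dissections were not separated from that of genotype. Of 18079 genes tested, 1758 were higher and 1897 were lower at an edgeR adjusted p under 0.05. Most changes were small, since 64.6% of the called genes differed by less than 1.5-fold, while 199 genes were at least 2-fold higher and 364 at least 2-fold lower. In 7207 genes (39.9%) the 3 libraries of one group lay wholly above those of the other, against 10% by chance. The count of calls changed with the libraries used. Without KO 1 there were 3752 higher and 3804 lower genes, and without WT 1, WT 2, WT 3, KO 2 or KO 3 in turn there were 1960, 1210, 1191, 1363 and 1387 called genes in total.

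**Figure D1:**
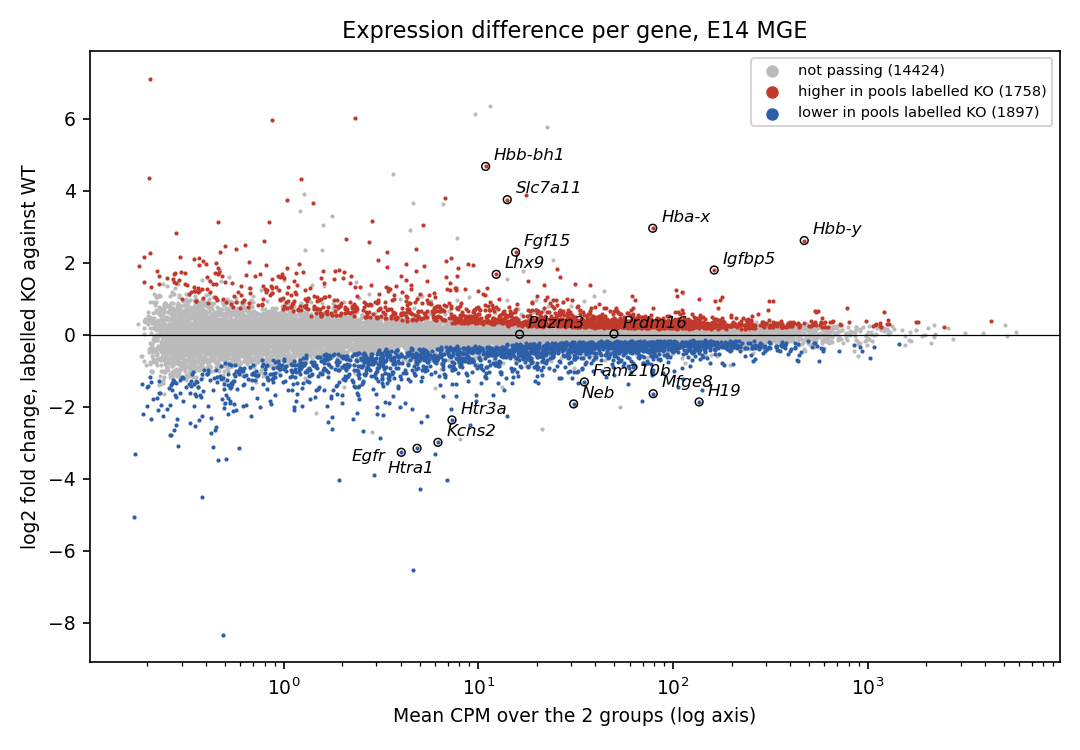
Each point is 1 of the 18079 tested genes, with its mean CPM over the 2 groups (log axis) and its log2 fold change in the pools labelled KO against WT. Red points (1758) were higher and blue points (1897) lower at an edgeR adjusted p under 0.05, grey points did not pass, and circled genes are named, with Prdm16 and Pdzrn3 at 0.02 and 0.01.

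Among the genes with the strongest rise were transcripts of early red blood cells and of forebrain patterning. Hbb-bh1 (25.5-fold), Hba-x (7.76-fold) and Hbb-y (6.12-fold), which encode embryonic globins, rose, with Hbb-y going from 133 ± 24.1 to 812 ± 208 CPM (edgeR adjusted p = 0.000736). Kel, a red cell surface antigen gene, rose 12.7-fold from 0.203 ± 0.0625 CPM. Fgf15, a growth factor gene of the embryonic forebrain, rose 4.89-fold (5.29 ± 0.622 to 25.8 ± 3.15 CPM, edgeR adjusted p = 1e-05). Igfbp5, which encodes a binding protein of insulin-like growth factors, rose 3.47-fold to 253 ± 26.4 CPM, and the homeobox gene Lhx9 rose 3.2-fold to 18.8 ± 1.53 CPM. Hsd3b6, a steroid dehydrogenase gene, rose 8.98-fold to 5.11 ± 0.16 CPM. Lama1, a laminin chain gene, rose 1.89-fold and Fndc3c1 rose 4.1-fold. Cel, Slc7a11, Dbx1, Nhlh1 and Mid1-ps1 met the rule with less even libraries, and each lost its call in at least 1 alternative. Slc7a11, a cystine transporter gene, went from 1.93 ± 0.225 to 26.3 ± 16.3 CPM (edgeR adjusted p = 0.0105), and the homeobox gene Dbx1 went from 0.595 ± 0.313 to 3.6 ± 1.82 CPM (edgeR adjusted p = 0.00643). Cel, a lipase gene, reached 2.35 ± 2.09 CPM (edgeR adjusted p = 0.0238), Nhlh1, a neuronal helix-loop-helix gene, 4.68 ± 3.3 CPM (edgeR adjusted p = 0.0495) and the pseudogene Mid1-ps1 5.67 ± 2.98 CPM (edgeR adjusted p = 0.0188). Mid1-ps1 is annotated on chromosome Y, yet it had 6.63 CPM in KO 3, where other Y-linked genes were at 0.36 CPM, and 2.32 CPM in KO 1. It therefore does not follow those Y-linked genes. The source of its reads was not examined, and its value is uncertain.

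Among the genes with the strongest fall were receptors, a potassium channel subunit and matrix proteins. Egfr, the epidermal growth factor receptor gene, fell from 7.3 ± 1.65 to 0.751 ± 0.308 CPM, which was 9.64-fold lower (edgeR adjusted p = 0.000121). The serine protease gene Htra1 was 8.93-fold lower and the potassium channel gene Kcns2 7.96-fold lower, from 11 ± 1.58 to 1.39 ± 0.423 CPM. Hepacam, a glial adhesion gene, was 7.3-fold lower, and Ccdc80 and Adamts15, of the extracellular matrix, were 6.43-fold and 5.36-fold lower. Npy1r (6.12-fold), Htr1a (5.4-fold) and Htr3a (5.17-fold), which encode receptors of neuropeptide Y and serotonin, were lower as well. The imprinted noncoding RNA H19 fell from 214 ± 8.28 to 58.6 ± 4.65 CPM and had the smallest p of the named genes (edgeR adjusted p = 7.86e-07). Fam210b (2.49-fold), Neb (3.8-fold), Mfge8 (3.12-fold) and Prkca (2.25-fold) were lower at edgeR adjusted p-values between 5.14e-06 and 2.19e-05. The pseudogene Pcna-ps2 was 16.4-fold lower, but its reads can be shared with Pcna and its value is uncertain.

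**Figure D2:**
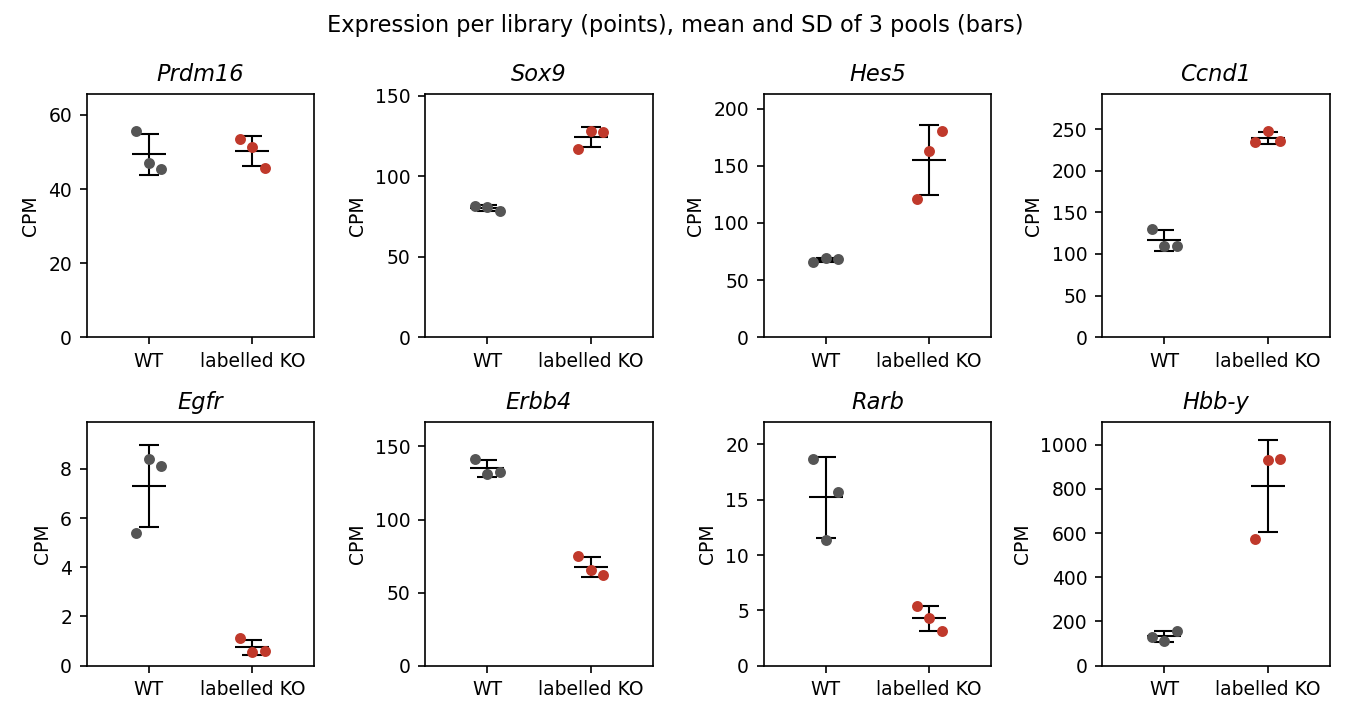
CPM of 8 named genes in each library (points), with the mean and SD of 3 pools (bars), for WT and for the pools labelled KO. Prdm16 overlaps between the groups, Sox9, Hes5, Ccnd1 and Hbb-y are higher in each pool labelled KO, and Egfr, Erbb4 and Rarb are lower in each.

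Radial glia are the progenitors of the ventricular zone. Of 21 tested members of this list, 16 rose, 1 fell (Slc1a3) and 4 did not pass, and adjusted over the list alone 18 rose and 1 fell. Sox9 rose 1.55-fold to 124 ± 6.14 CPM, Nes, which encodes nestin, 1.59-fold to 684 ± 20.3 CPM, Ednrb 1.49-fold and Id4 1.47-fold. The median log2 fold change was 0.53 (camera adjusted p = 8.61e-11, and adjusted p = 0.287 with an estimated correlation). In the Notch list, 10 of 23 members rose, 1 fell and 12 did not pass (12 and 3 adjusted over the list alone). The Notch target genes Hes5 (2.29-fold), Hes1 (1.87-fold) and Hey1 (1.85-fold) and the ligand gene Dll1 (1.62-fold) rose, with a list median of 0.23 (camera adjusted p = 0.00209, and adjusted p = 0.314 with an estimated correlation). Hes1 and Hes5 belong to both lists, so the results are not independent. Hes5 is also in the list of genes near Prdm16, and whether its place near the floxed allele contributes was not tested.

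Of 16 genes of subventricular zone progenitors 8 rose, 3 fell and 5 did not pass (10 and 3 adjusted over the list alone). Dll1, Dll3 and Mfng, which rose, are also in the Notch list, so these results are not independent either. Gsx2, a homeobox gene of ventral progenitors, rose 1.98-fold, Rgs16 1.62-fold and Hes6 1.4-fold, while the list median was 0.24 (camera adjusted p = 0.00705, and adjusted p = 0.647 with an estimated correlation). In the G1/S list 6 of 24 members rose, 2 fell and 16 did not pass (7 and 2 adjusted over the list alone; camera adjusted p = 0.00209, and adjusted p = 0.647 with an estimated correlation). The D-type cyclins moved apart, as Ccnd1 rose 2.06-fold to 239 ± 7.57 CPM and Ccnd2 was 1.66-fold lower at 424 ± 73.3 CPM. E2f2 was 1.23-fold lower and Gins2, a replication gene, rose 1.34-fold. In the G2/M list Plk1 rose 1.22-fold, Kif11 was 1.26-fold lower and 22 of 24 members did not pass (0 and 1 adjusted over the list alone, camera adjusted p = 0.699).

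In the 3 neuronal lists, most of the members that passed were lower. Of 22 postmitotic neuron genes 8 fell, 1 rose and 13 did not pass (9 and 2 adjusted over the list alone). Syt4, a synaptotagmin gene, was 1.73-fold lower, Nrxn3, which encodes a synaptic adhesion protein, was 1.35-fold lower, and Snap25, of the vesicle fusion machinery, was 1.25-fold lower (camera adjusted p = 0.011, and adjusted p = 0.647 with an estimated correlation). Among 17 GABAergic genes 9 fell, 3 rose and 5 did not pass (10 and 3 adjusted over the list alone). The potassium channel genes Kcnc2 and Kcnc1 were 2.04-fold and 1.57-fold lower, Pde4dip was 1.73-fold lower and Gad1, which makes GABA, was 1.29-fold lower at 205 ± 1.06 CPM (camera adjusted p = 0.00217, and adjusted p = 0.486 with an estimated correlation). Of 25 migration and guidance genes 10 fell and 15 did not pass (11 fell and 1 rose adjusted over the list alone). Erbb4, a neuregulin receptor gene of migrating interneurons, fell from 135 ± 5.61 to 67.4 ± 6.88 CPM, Plxna4 was 2.35-fold lower, Epha4 1.65-fold lower and Sema3f 1.41-fold lower (camera adjusted p = 0.00209, and adjusted p = 0.647 with an estimated correlation).

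Lists of regional identity did not share a direction. Those of the cortex and of the lateral and caudal ganglionic eminences mark tissue neighbouring the MGE. The amount of such tissue in the dissections may contribute to their values, which was not tested. Of 19 genes of the lateral and caudal ganglionic eminences 12 fell, 1 rose and 6 did not pass (13 and 2 adjusted over the list alone). Ikzf1 was 4.03-fold lower, Rarb, a retinoic acid receptor gene, 3.59-fold lower and Penk, which encodes proenkephalin, 2.62-fold lower, and the list median was -0.92 (camera adjusted p = 7.29e-05, and adjusted p = 0.647 with an estimated correlation). In the cortical excitatory list 6 of 14 members rose and 8 did not pass (6 rose and 1 fell adjusted over the list alone), with a median of 0.94 (camera adjusted p = 0.00215, and adjusted p = 0.647 with an estimated correlation). Tbr1, a transcription factor gene of early cortical neurons, went from 23.8 ± 6.41 to 40.7 ± 4.36 CPM, Emx1 rose 3.06-fold to 1.49 ± 0.0986 CPM and Emx2 1.25-fold. Neurog1 went from 0.0259 ± 0.0041 CPM, a level near 1 count per library, to 1.71 ± 1.41 CPM, so no fold is given. MGE identity genes had no common direction, as 5 of 15 rose, 3 fell and 7 did not pass (5 and 5 adjusted over the list alone, camera adjusted p = 0.913). Maf, a transcription factor gene of MGE interneurons, was 2.61-fold lower and Etv1 1.51-fold lower, while Gbx2 rose 2.12-fold and Sst, which encodes somatostatin, 1.49-fold.

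**Figure D3:**
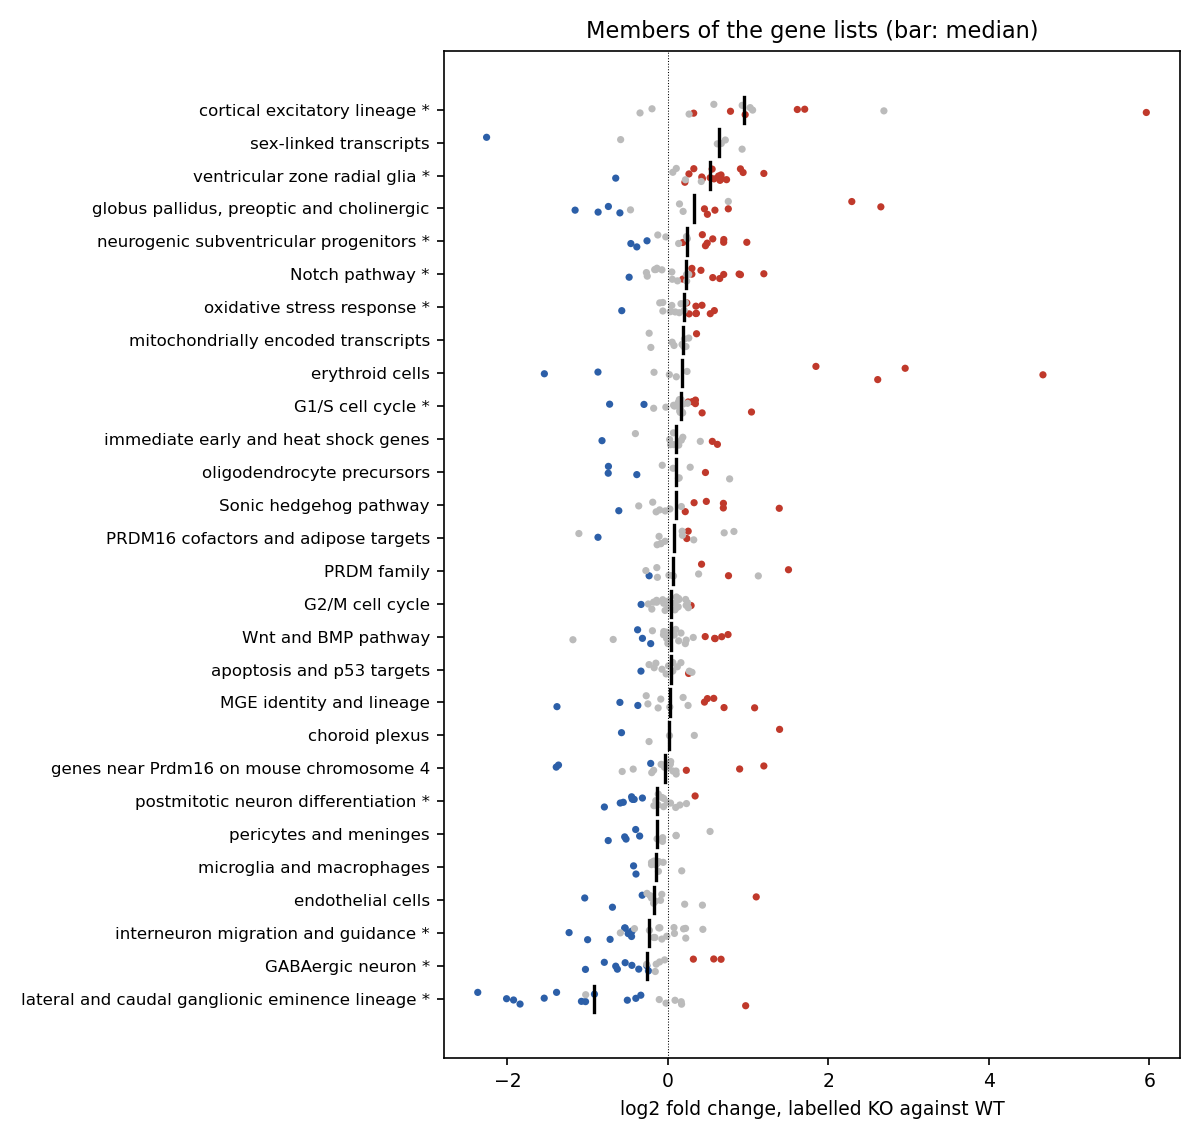
Log2 fold change in the pools labelled KO against WT of each tested member of the 28 gene lists (points), with the list median (bar). Red members were higher and blue members lower at an edgeR adjusted p under 0.05, and an asterisk marks the 10 lists with a camera adjusted p under 0.05, of which 6 were higher and 4 lower.

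Of the 28 lists 10 passed camera with its preset correlation of 0.01, and 0 passed with an estimated correlation. With an estimated correlation 2 lists had an unadjusted p under 0.05, radial glia (camera p = 0.0102) and Notch (camera p = 0.0224). In fry, which asks whether a list's members move one way on balance, 3 of the 10 passed, namely radial glia (adjusted p = 0.00358), Notch (adjusted p = 0.00542) and GABAergic neuron (adjusted p = 0.0059). Unlike camera, fry does not compare a list with the other genes, and 20.2% of all tested genes were called. A pass in fry therefore does not show that a list moved more than other genes. The PRDM family (fry adjusted p = 0.0059) and the Wnt and BMP list (fry adjusted p = 0.0172) passed fry but not camera. In the oxidative stress list 8 of 19 members rose, 1 fell and 10 did not pass (10 and 1 adjusted over the list alone, camera adjusted p = 0.00274, and adjusted p = 0.647 with an estimated correlation). Ucp2, a mitochondrial carrier gene, rose 1.44-fold, Txn1 1.34-fold, Prdx1 1.27-fold and Gpx1 1.2-fold. Other lists did not pass camera although single members changed. Shh, the ligand gene of the hedgehog pathway, rose 2.62-fold to 54.3 ± 12.1 CPM and Gli1 rose 1.61-fold (6 of 14 members rose and 1 fell, camera adjusted p = 0.204). Mecom, the closest relative of Prdm16, rose 2.83-fold from 2.87 ± 0.457 to 8.09 ± 0.0805 CPM (3 of 12 PRDM genes rose and 1 fell, camera adjusted p = 0.204). Fzd1 rose 1.5-fold in the Wnt and BMP list (5 of 24 rose and 3 fell, camera adjusted p = 0.292). Gbx1 rose 1.68-fold and Chat was 2.23-fold lower in the pallidal, preoptic and cholinergic list (6 of 14 rose and 4 fell, camera adjusted p = 0.204). Sesn1 was 1.26-fold lower in the apoptosis list (1 of 14 rose and 1 fell, camera adjusted p = 0.913), and Ppargc1a was 1.83-fold lower in the list of cofactors and adipose targets (2 of 14 rose and 1 fell, camera adjusted p = 0.679). Jun rose 1.47-fold among immediate early and heat shock genes (2 of 12 rose and 1 fell, camera adjusted p = 0.204), and Trp73 1.86-fold among genes near Prdm16 (3 of 19 rose and 3 fell, camera adjusted p = 0.967). Hes5, of the Notch list, was also among the genes near Prdm16 that rose. The hedgehog list passed without KO 3 (camera adjusted p = 0.0488) and the pallidal list without WT 2 (camera adjusted p = 0.0418).

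Markers of other cell types were measured beside these groups. In red blood cell genes 4 of 10 members rose, 2 fell and 4 did not pass (camera adjusted p = 0.192). Embryonic globins made up 22.4 ± 3.14% of all globin counts in WT and 71.5 ± 1.98% in the pools labelled KO (exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Without Hbb-bs and Hbb-bt, whose levels depend on the mouse strain, the share was 38.9 ± 3.92% and 78.2 ± 0.902% (exact two-sided permutation p = 0.1). Total globin was 672.3 ± 31.9 CPM in WT and 1356 ± 324 CPM in the pools labelled KO, with each of the latter above each WT pool (exact two-sided permutation p = 0.1). Hba-x rose 7.76-fold, while Hba-a1 (188 ± 7 and 222 ± 54.5 CPM) and Hba-a2 (46.8 ± 2.88 and 47.4 ± 8.96 CPM), near-identical genes that can share reads, did not pass. Hbb-bs and Hbb-bt were 2.91-fold and 1.83-fold lower, and these values are uncertain for that reason. Cldn5 and Slco1c1, of brain endothelium, were 1.61-fold and 2.05-fold lower (3 of 13 endothelial genes fell and 1 rose, camera adjusted p = 0.108). Pdgfrb was 1.32-fold lower in the pericyte list (5 of 11 fell, camera adjusted p = 0.0874) and Csf1r 1.35-fold lower in the microglia list (2 of 11 fell, camera adjusted p = 0.182). Cspg4, which is in both the pericyte and the oligodendrocyte precursor lists, was 1.68-fold lower. The oligodendrocyte precursor list had 1 of 10 members higher and 3 lower (camera adjusted p = 0.913), with a median of 0.10 but a mean of -0.01 and a downward camera direction. Otx2 rose 2.62-fold in the choroid plexus list (1 of 5 rose and 1 fell, camera adjusted p = 0.679), and mt-Nd1 1.28-fold among mitochondrial transcripts (1 of 10 rose, camera adjusted p = 0.199). Without KO 1 the endothelial (camera adjusted p = 0.0275) and pericyte (0.0292) lists passed as lower, and the red blood cell (0.0383) and mitochondrial (0.0011) lists as higher.

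The libraries differed in ways beyond the groups. The first principal component held 55.9% of the variance and separated the groups, and the second held 16.1% and set KO 1 (-34.99) apart from KO 2 (11.58) and KO 3 (12.4). Correlations of log CPM ran from 0.9902 to 0.9954 within groups and from 0.9829 to 0.988 between them. Xist, made from the inactive X chromosome, was at 1.92 CPM in KO 1 and 1424 CPM in KO 3, and Y-linked genes were at 238.5 CPM in KO 1 and 0.36 CPM in KO 3. The other pools had both kinds of transcript. In the sex-linked list 1 of 6 members fell (Tsix, which overlaps Xist on the other strand), and its median of 0.64 and mean of 0.01 had the opposite sign to camera (adjusted p = 0.204).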

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

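The male share covariate, the protein-coding restriction and the length correction were chosen after seeing the data. Of 536 pairs of a ranked gene and an alternative, 510 kept direction and side of the threshold, 26 lost the call and 0 reversed; the losses fell on Cel, Slc7a11, Dbx1, Nhlh1 and Mid1-ps1. Prdm16 had log2 fold changes from -0.03 to 0.14 over 18 alternatives (edgeR adjusted p from 0.208 to 0.972). Leaving out 1 library gave 464 to 3752 higher and 727 to 3804 lower genes, with the highest counts without KO 1 and fewer samples in each such fit. The replicate number as a block gave 862 higher and 1219 lower genes. Deviations of same-numbered libraries correlated at -0.08, -0.12 and 0.03, which gives no sign that the numbers pair the samples. A threshold of 0.01 gave 360 and 583, and one of 0.1 gave 2732 higher genes, by construction. A test against a fold of 1.2 gave 310 and 540, since it asks for a larger change. The male share covariate gave 2974 and 3285; the cause was not tested. Other scalings, filters and tools gave counts within 1.5 times. Of the 28 lists, 0 passed with an estimated correlation and 5 passed fry, which tests another hypothesis; 3 of these were among the 10 called by camera. Each of the 10 called lists passed in the same direction in 13 of 13 other camera settings, all of which kept the preset correlation of 0.01. These settings therefore do not vary the assumption on which the calls depend. The estimated correlations of the 10 lists ran from 0.00836 (Notch) to 0.649 (G1/S). Of the lists that camera did not call, 4 passed without KO 1 (endothelial, pericyte, red blood cell and mitochondrial), the pallidal list without WT 2 and the hedgehog list without KO 3. The male share covariate added the endothelial (camera adjusted p = 0.0414), mitochondrial (0.00744) and sex-linked (0.00719) lists, the stricter filter the endothelial list (0.0335), and removal of the length trend the PRDM (0.0474) and microglia (0.0412) lists. Genes near the count floor, such as Neurog1 and Cel, are limited by depth.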

Other observations

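The lists in this part were written after a first look at the most changed genes, and the tests of embryo age, of blood, of length removal, of pseudogenes, of a swapped library and of remaining exons were chosen only after the result was seen. Of 20 imprinted genes 11 rose, 1 fell and 8 did not pass (camera adjusted p = 3.04e-05, and adjusted p = 0.108 with an estimated correlation). H19 was left out of that list although its fall had been seen, and with it 11 of 21 rose and 2 fell (camera adjusted p = 0.000413, and adjusted p = 0.109 with an estimated correlation). Dlk1 rose 1.92-fold, Peg10 1.53-fold, Mest 1.48-fold and Cdkn1c, a cell cycle inhibitor gene, 2.34-fold, while Igf2 was 2.03-fold lower and the neighbouring H19 3.65-fold lower. Of 9 early progenitor genes 5 rose and 1 fell (camera adjusted p = 0.000339, and adjusted p = 0.108 with an estimated correlation), among them Igf2bp2 (1.67-fold), Igf2bp1 (1.49-fold) and Lin28b (1.55-fold), which encode RNA-binding proteins of early development. Of 17 late progenitor and astrocyte genes 8 fell, 1 rose (Fgfr3, 1.56-fold) and 8 did not pass (camera adjusted p = 0.00365, and adjusted p = 0.109 with an estimated correlation), with Nfix 2.17-fold, Bcan 1.71-fold and Sparcl1 1.53-fold lower.

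The first pattern is the breadth of the difference, with 3655 called genes. Different amounts of blood of the same makeup are opposed as a cause for these alpha globins only. Hba-x rose by at least 2.72 more on the log2 scale (SE 0.28) than Hba-a1 and Hba-a2. How many of the other calls follow blood content was not tested. Total globin was higher in the pools labelled KO, and more blood there is not excluded. The sex makeup of the pools was not decided by its test. With the male share as a covariate, calls rose to 6259, which met neither outcome written in advance. Of the main calls, 3631 were kept in the same direction, so a linear trend on male share did not remove them. The male share was highest in KO 1 and lowest in KO 3. Leaving out KO 1 alone also raised the calls, to 7556, so the rise itself cannot be read as a result about sex. Log2 fold change correlated with exonic length across genes at -0.27, between the bounds set in advance for a bias and for none (GC content 0.042), and removing the length trend left 3562 calls, 2882 of them shared, so length is not the whole cause but may contribute. Younger embryos in the pools labelled KO remain a candidate explanation that the design cannot settle. The lowest embryonic globin share there without Hbb-bs and Hbb-bt was 77.5% against at most 42.9% in WT. The differences in radial glia, Notch and neuronal genes cannot be told apart from a difference in age either. Diencephalic tissue in the dissections also stays open, with a list median of 0.781 but 4 of 10 members higher and 1 lower (camera adjusted p = 0.00227, and adjusted p = 0.15 with an estimated correlation). Among the higher members was Gbx2, which is also in the MGE identity list. Other neighbouring tissue stays open too, as the cortical list (median 0.94) and the lateral and caudal ganglionic eminence list (median -0.92) mark such tissue. An effect of losing Prdm16 on brain cells stays open and untested because age and genotype cannot be told apart here. Globins come from blood, while Nkx2.1-Cre drives recombination in MGE progenitors. For the globins, the rise in the embryonic share from 38.9% to 78.2% without Hbb-bs and Hbb-bt thus argues against a direct effect of the deletion. An indirect effect on the pace of the whole embryo was not tested. Chance cannot be judged from splits of the libraries, since 10 splits of 6 libraries are too few (1 split, the real one, called as many genes, and the highest other called 0).

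The second pattern is that Prdm16 was not lower in the pools labelled KO. A swap of 1 library between the groups is opposed, since each library correlated better with its own group, by at least 0.0028. Reads from exons that the deletion leaves in place may hide a loss, and gene-level counts with a lower bound of the fold of 0.884 cannot decide this. Counts per exon were not analysed here.

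The third pattern is the share of pseudogenes among the genes with the largest folds, 15% of called genes with a fold over 4 against 4.35% of tested genes, although of all 786 tested pseudogenes only 80 were called, a smaller share than the 20.2% of all tested genes. Calls were not in excess around the floxed allele, since genes within 10 Mb of Prdm16 were called 0.725 times as often as others (14.7% and 20.3%, Fisher's exact p = 0.0734). That count took genes of any type and fold, and the positions of the pseudogenes with large folds were not examined. It therefore cannot decide whether a strain haplotype there contributes to this pattern. Strain variants elsewhere, or reads shared with parent genes, may still contribute, as the ratio of 3.45 lay between the values set for and against them.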
